A study of Mus musculus with 23 samples.

How the data were processed

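RNA from the hypothalamus of 23 male mice was labelled and hybridised to Illumina MouseRef-8 version 2 BeadChips. Per the file headers, the authors exported bead intensity per probe and a detection p-value per probe from BeadStudio (3.4.0 in the submitters' processing notes), with no background subtraction and no normalization. The intensity values are on a linear scale. The detection p-value deposited beside each intensity compares the probe with the array's negative controls. The authors also deposited a score per probe and array. It was tested against the intensities and equals log10 intensity minus the array's mean over the array's SD, to within 5e-10, with array medians from 0.309 to 0.476. Scores were given for 14194 probes and left blank on all arrays for 11503. The lowest detection p of a blank probe was 0.0201, the rule for blanking is not given in the sources used here, and genes were not centred. No slide, scan date or batch is named in the sources used here.

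The main analysis began from the intensities. Background correction by normexp with controls inferred from the detection p-values, an offset of 16, quantile normalization and log2 were applied with neqc of limma 3.58.1 in R 4.3.3. Probes with a detection p under 0.05 on at least 3 arrays were kept, 14085 of 25697. Symbols were updated through the Entrez gene ID, which matched 23681 probes to a RefSeq gene table of the GRCm38.p6 assembly, and 2016 probes kept the symbol of the file. One tested probe with a symbol damaged by a spreadsheet was left unnamed. No coordinates are given, since no build is named for the probes. A probe reads 1 part of a transcript, so probes of 1 gene can disagree. For genes, the probe of smallest p was named, and for lists the probe of highest mean represented the gene.

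Samples were grouped by genotype and agent from their labels. The mice had separate numbers, so no pairing across groups existed and each array is 1 mouse. A group-means model over all 23 arrays shared 1 estimate of the spread (15 residual degrees of freedom, 4.26 prior), with moderated statistics and an intensity trend (limma eBayes) and Benjamini-Hochberg adjustment over the tested probes at 0.05. The 14 comparisons were genotype in saline mice, genotype averaged over agents, each agent against saline in each genotype, each agent by genotype interaction, and the agents against each other in N171-82Q mice. Where a probe was undetected on every array of 1 group, the fold is given as a lower bound. It sets the brighter group's mean against the mean, per array, of the higher of the lowest detected signal and the probe's own. Gene lists (15 pathway lists and 14 lists of cell or tissue markers, 573 genes, 440 with a tested probe) were tested with camera of limma at a preset correlation of 0.01 and again with the correlation estimated, adjusted over the 29 lists of a comparison, 406 tests in all. Lists overlap. The signature score used exact 2-sided permutation tests.

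Genes were named by a rule set before the data were examined. It took the 10 largest rises and falls among called probes where 20 or more were called, all called probes where fewer were, and otherwise the 5 rises and 5 falls of smallest p, described as not passing. It added Prnp and Htt in every comparison, and per list up to 4 called members or 2 members of smallest p. Not every gene so chosen is printed.

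Alternatives set before the data were examined were no background correction, per-array Z-scores in place of quantile normalization, no detection filter, a stricter one (detection p under 0.01 on all arrays of a compared group), a fit on only the groups compared, array weights, the deposited scores, and leaving out each mouse. For lists they were an estimated correlation and all probes of a gene, and for the signature 50 and 200 probes. Slide as a block was planned and could not be run. Array weights used limma's gene-by-gene method, because the default fit did not converge. Added after the data were seen were leaving out the arrays labelled WT GLP-1Tf 9 and N171-82Q Ex-4 24, array brightness as a covariate, and agent effects averaged over genotypes.

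The procedure was tested on simulated data with 67 probes changed by 0.5 (log2), 67 by 1 and 66 by 2 among 14085. For genotype averaged over agents, 76.1% of probes changed by 0.5, 95.5% of those changed by 1 and 100% of those changed by 2 were called, with 9 unchanged probes. For GLP-1Tf in N171-82Q mice (3 against 3) these shares were 10.4%, 73.1% and 100%, with 8 unchanged probes. Simulated probes varied independently of each other, which real probes do not. A simulated shift of 1 list was called, with 2 of 28 other lists, which share members with it.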

Results

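Hypothalamic gene expression was measured on Illumina MouseRef-8 BeadChips, which read each transcript with short probes on beads. The mice were male N171-82Q mice, a model of Huntington's disease that expresses an N-terminal fragment of human huntingtin with an expanded glutamine stretch from a mouse prion promoter vector, and wild-type (WT) mice of the same B6/C3 background. Both genotypes received once-daily subcutaneous injections for 5 weeks from 2 months of age. The agents were saline, insulin (5 units of the long-acting form Lantus), GLP-1Tf (a fusion of glucagon-like peptide 1 with transferrin, 1 mg/kg) or Ex-4 (exendin-4, a peptide agonist of the GLP-1 receptor, 300 µL of 0.1 µmol/L). The 23 arrays formed 8 groups of 3 mice, except WT saline with 2 mice. Mean bead intensity per array ran from 267 to 644, and 12057 to 13145 of 25697 probes per array were detected above the negative controls. The number of arrays limits the precision of every comparison. Arrays of the same group correlated with a median Pearson r of 0.983 over the tested probes, against 0.980 for arrays of different groups (22 and 231 pairs; r is across probes, which are not independent replicates).

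The transgene's vector made Prnp, the prion protein gene, a check of the labels. Prnp lay at 14.05 to 14.63 on 10 WT arrays and at 14.96 to 15.20 on 11 N171-82Q arrays (log2 intensity, 1 probe). On these 11 arrays it ranked 1 to 3 among all probes, against 11 to 32 on the 10 WT arrays, and quantile normalization fixes the value of a rank, so the size of its changes below is capped. The array labelled WT GLP-1Tf 9 read 14.96, inside the N171-82Q range. The array labelled N171-82Q Ex-4 24 read 14.36, inside the WT range. Both kept their labels in every comparison, and each count below was also taken without the pair, a setting chosen after their values were seen. The Htt probe showed a genotype difference of -0.08 ± 0.14 (log2, SE, limma adjusted p = 0.821), and since it lies in the 3' part of the mouse transcript it checked nothing about a human N-terminal fragment.

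**Figure D1:**
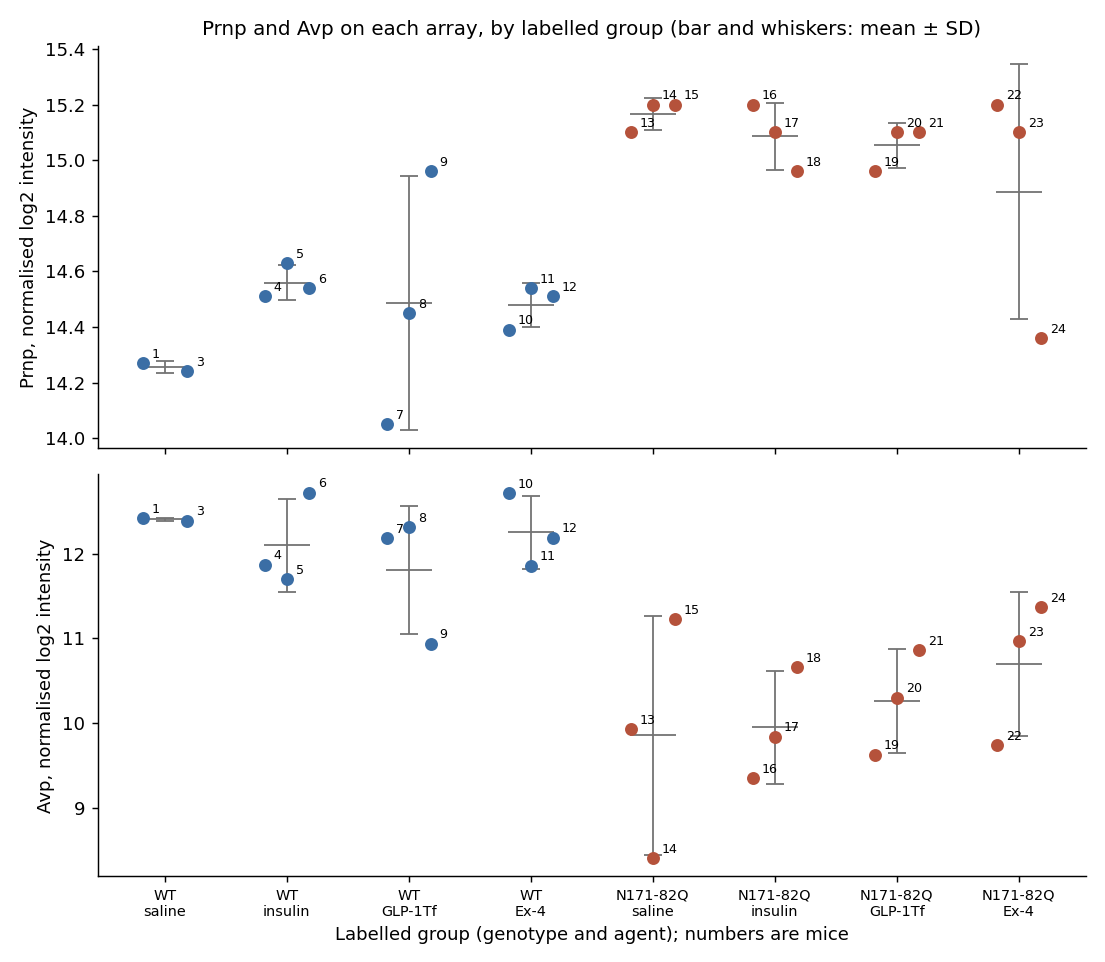
Normalised log2 intensity of Prnp (top) and Avp (bottom) on each of the 23 arrays, by labelled genotype and agent; points are mice with their numbers, bars and whiskers are the group mean ± SD. Prnp of the array labelled WT GLP-1Tf 9 (14.96) and of the array labelled N171-82Q Ex-4 24 (14.36) lies in the range of the other genotype.

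The genotype comparison averaged over the 4 agents asked which hypothalamic transcripts differ between N171-82Q and WT mice whatever the injection. Messenger RNAs of some hypothalamic peptides fell in N171-82Q mice, while others did not pass. Avp, which encodes the antidiuretic hormone vasopressin, fell most, from 12.12 ± 0.51 in WT mice (SD, n = 11) to 10.19 ± 0.87 (SD, n = 12), a log2 change of -1.95 ± 0.29 (SE, adjusted p = 0.00576). Pomc, the precursor of the satiety peptide alpha-MSH, fell by 1.18 ± 0.28 (adjusted p = 0.0491), and Vip, a peptide of the suprachiasmatic nucleus, fell by 1.05 ± 0.23 (adjusted p = 0.0346). Ghrh, which encodes growth hormone-releasing hormone, fell by 0.92 ± 0.16 (adjusted p = 0.0135). Oxt, the oxytocin gene, had a change of 0.05 ± 0.15 (adjusted p = 0.905).

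Of 14085 detected probes tested with limma, 113 were called at a false discovery rate of 0.05, 27 higher and 86 lower in N171-82Q mice. They named 106 genes. The 10 genes that fell most also held Cartpt, the precursor of the appetite-suppressing peptide CART (-0.92 ± 0.15, adjusted p = 0.00818), Trh, thyrotropin-releasing hormone (-0.76 ± 0.15, adjusted p = 0.0229), and Hcrt, the orexin precursor (-0.74 ± 0.16, adjusted p = 0.0391). The others were Tnxb, an extracellular matrix protein (-0.94 ± 0.11, adjusted p = 0.000566), Socs3, an inhibitor of leptin and cytokine signalling (-0.81 ± 0.11, adjusted p = 0.00174), and Crabp1, a retinoic acid-binding protein (-0.75 ± 0.12, adjusted p = 0.00818). These 3 probes were dim in N171-82Q mice, where that of Tnxb was detected on 1, that of Socs3 on 2 and that of Crabp1 on 2 of 12 arrays. Another Tnxb probe, detected on all 23 arrays, fell by 0.70 ± 0.10 (adjusted p = 0.00537). Avp, Vip, Tnxb, Ghrh, Cartpt, Socs3, Trh, Crabp1 and Hcrt lay below the WT mean on 12 of 12 N171-82Q arrays, and Pomc on 11. The probes were picked on these same arrays, so these counts describe the calls and add no separate support. The rises were smaller. Zbtb46 (0.62 ± 0.14), Prnp (0.61 ± 0.10), Olfr646 (0.50 ± 0.10), Nqo1, an antioxidant quinone reductase (0.49 ± 0.11), and Ccm2 (0.45 ± 0.10) led, with adjusted p-values from 0.00747 to 0.0462. Pcdhb7, Casp1, Steap2, 3830406C13Rik and Copg1 followed with changes from 0.37 to 0.42 on their probes of smallest p. Of the 2 other called Copg1 probes, 1 rose more (0.53 ± 0.11, adjusted p = 0.0363). For 3830406C13Rik the 3 probes ran from 0.04 to 0.38. Prnp lay above the WT mean on 11 of 12 N171-82Q arrays, and since its change is capped, its place among the rises is not exact.

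Among the lists fixed before the data were examined, 5 of 14 measured hypothalamic neuron genes were called, all lower, and 9 were not (10 lower and 0 higher when adjusted over the list alone). The list's median change was -0.52 (camera adjusted p = 9.14e-10; adjusted p = 0.0242 with an estimated correlation). Of 17 neuroendocrine peptides, 7 were called, all lower, among them Avp, Sst (somatostatin, -0.71 ± 0.12), Ghrh and Grp (-0.62 ± 0.11). Adjusted over the list alone, 10 were lower and 1 was higher. This list had a median of -0.38 (adjusted p = 1.56e-07; adjusted p = 0.0242 with an estimated correlation). Of 14 appetite neuropeptides, 4 were called, all lower: Cartpt, Trh, Hcrt and Pomc (7 lower and 0 higher when adjusted over the list alone; median -0.32, adjusted p = 3.44e-07, adjusted p = 0.0462 with an estimated correlation). The 3 lists share members. Agrp and Npy, the appetite-stimulating peptides of the arcuate nucleus, had changes of -0.36 ± 0.31 (adjusted p = 0.613) and -0.29 ± 0.21 (adjusted p = 0.527). Striatal-type genes known to be reduced in Huntington's disease models were lower too (21 measured, 2 called, both lower; 3 lower and 0 higher when adjusted over the list alone; median -0.16, adjusted p = 0.000127, adjusted p = 0.0322 with an estimated correlation), with Itpka at -0.48 ± 0.10 and the transcription factor Bcl11b at -0.43 ± 0.10.

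Of the markers of other cell types, microglial genes were lower as a list (11 measured, 0 called, 4 lower when adjusted over the list alone; median -0.20, adjusted p = 2.84e-05; adjusted p = 0.0462 with an estimated correlation). Csf1r, the receptor that maintains microglia, had a change of -0.32 ± 0.08 (adjusted p = 0.0693) and the complement gene C1qb one of -0.40 ± 0.11 (adjusted p = 0.101). A further 10 lists passed with the preset correlation and not with an estimated one. Their medians were -0.31 for meninges and fibroblast (adjusted p = 0.315 with an estimated correlation), -0.25 for pituitary (adjusted p = 0.0790), -0.20 for immediate early genes (adjusted p = 0.184), -0.14 for striatum (adjusted p = 0.220) and -0.13 for synaptic genes (adjusted p = 0.131). Those for incretin, insulin and leptin signalling (-0.10, adjusted p = 0.0802), inflammation and interferon (-0.10, adjusted p = 0.252), circadian clock (-0.08, adjusted p = 0.160) and chaperones and unfolded protein response (-0.08, adjusted p = 0.220) were smaller, all p-values with an estimated correlation. Thalamus markers were the 1 higher list (median 0.44, adjusted p = 0.0446; adjusted p = 0.400 with an estimated correlation), with Tcf7l2 at 0.59 ± 0.17 (adjusted p = 0.110), and had an adjusted p of 0.0893 without the 2 arrays with doubted Prnp. Adjusted over the list alone, 4 inflammation, 3 clock, 2 immediate early, 2 chaperone, 2 incretin-list, 1 striatum and 1 pituitary gene were lower, 1 thalamus gene was higher, and 0 synaptic or meningeal genes passed. Called members of these 10 lists were Socs3, Dbp, a clock output gene (-0.40 ± 0.06), the complement gene C3 (-0.57 ± 0.09), Serpina3n (-0.59 ± 0.11) and Npas4 (-0.51 ± 0.12). The other 14 lists had medians from -0.11 to 0.07 and did not pass (adjusted p from 0.105 to 0.993). They were proteasome and autophagy, oxidative phosphorylation (Ndufb2 called, -0.61 ± 0.12), glycolysis and glucose transport, cholesterol synthesis, glucocorticoid-responsive genes, DNA damage and apoptosis, oligodendrocyte and myelin, astrocyte, ependymal cell and tanycyte (Rarres2 called, -0.36 ± 0.08), choroid plexus, cortex and hippocampus (Itpka called), pan-neuronal, endothelial, and erythrocyte. Adjusted over the list alone, 3 oxidative phosphorylation, 3 cortex and hippocampus, 1 ependymal and 1 choroid plexus gene were lower, and 1 oxidative phosphorylation and 1 pan-neuronal gene were higher.

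The count depended on the arrays and settings used. It was 198 without the arrays labelled WT GLP-1Tf 9 and N171-82Q Ex-4 24, with 102 of the 113 probes among them, and 51 with no detection filter. With 1 mouse left out it lay between 23 and 72 for 17 mice, was 480 without N171-82Q saline 15, 342 without N171-82Q insulin 16 and 268 without WT GLP-1Tf 9, and between 77 and 107 without WT Ex-4 11, N171-82Q GLP-1Tf 21 or N171-82Q Ex-4 24. Avp, Tnxb, Cartpt, Socs3, Crabp1, Sst, Dbp and C3 were called in each of 31 alternatives, Prnp and Pcdhb7 in 29, Trh in 26, Hcrt in 14, Vip in 13, and Pomc, Nqo1, Ccm2 and Casp1 in 9. Ghrh and Grp were called in 30, Serpina3n in 29, Olfr646 in 22, Copg1 in 21 and Ndufb2 in 20. Zbtb46 and 3830406C13Rik were called in 14, Steap2 in 11, and Itpka, Bcl11b, Npas4 and Rarres2 in 10.

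**Figure D2:**
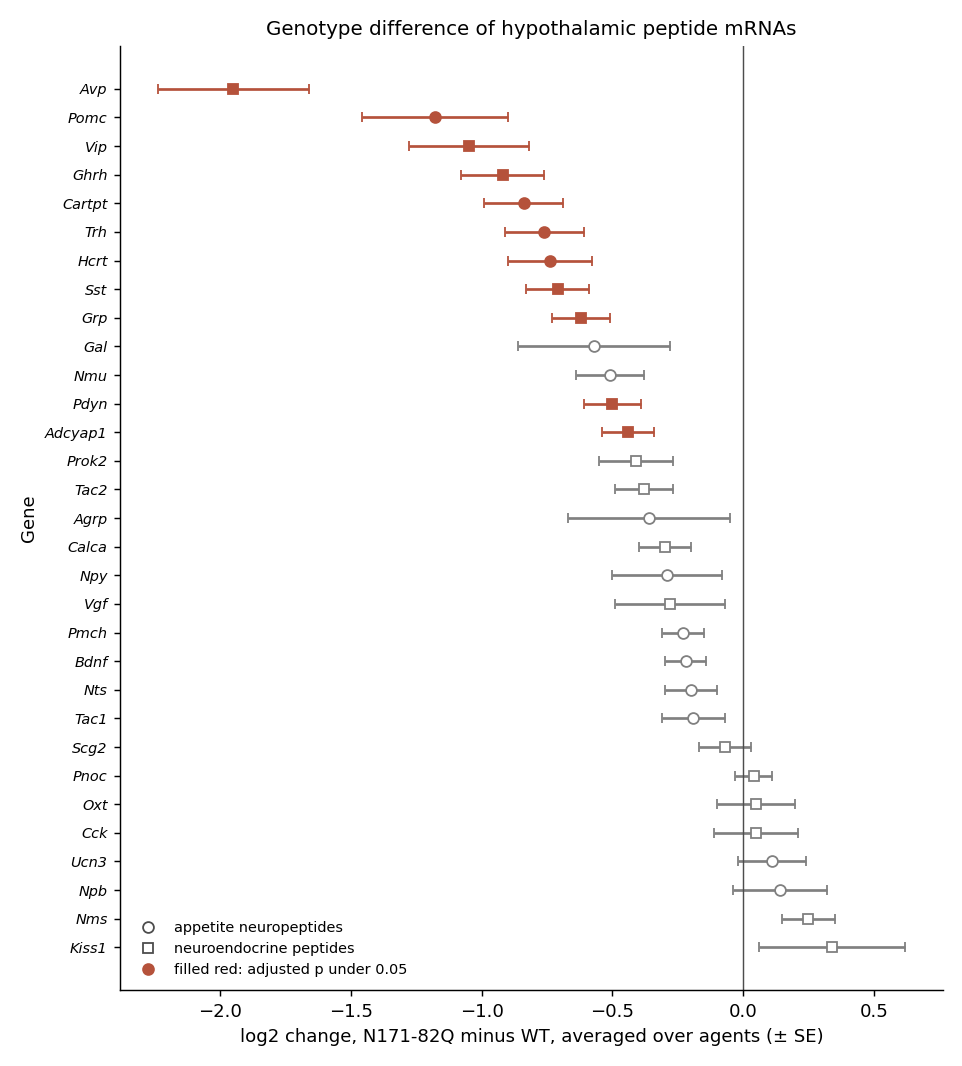
Genotype difference of each measured appetite neuropeptide (circles) and neuroendocrine peptide (squares) on the x axis, as log2 change of N171-82Q minus WT averaged over agents, ± SE, with the gene on the y axis; filled red symbols have a limma adjusted p under 0.05. Avp stands lowest at -1.95, and Oxt lies at 0.05.

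In saline-injected mice alone, the untreated background for the agents, no probe was called between 3 N171-82Q and 2 WT mice with limma, and 1330 had an unadjusted p under 0.05 where 704 were expected by chance. Avp read 9.86 ± 1.41 in N171-82Q mice (SD, n = 3) and 12.41 ± 0.02 in WT mice (SD, n = 2), a change of -2.55 ± 0.63 (adjusted p = 0.293). Probes of smallest p that did not pass were Nr4a2, an activity-induced nuclear receptor (-0.91 ± 0.16), Nasp (-1.48 ± 0.27), Pdpk1, a kinase of the insulin pathway (-0.71 ± 0.13), Tnxb and the pituitary hormone gene Prl, all with an adjusted p of 0.123. Prl was detected on 0 of 3 N171-82Q arrays and 2 of 2 WT arrays, at least 1.25-fold lower, and this Tnxb probe likewise at least 1.12-fold lower. Prl was also detected on 0 of 3 WT arrays with each of insulin, GLP-1Tf and Ex-4. Nr4a2 averaged 7.48 in WT saline mice, 6.57 in N171-82Q saline mice, 6.49 in WT Ex-4 mice and 6.66 in WT GLP-1Tf mice. For these 2 genes the WT saline arrays thus stood apart from other WT arrays too. On the higher side stood Poglut2 (0.82 ± 0.16), Cers5 (0.48 ± 0.10), Zw10 (0.94 ± 0.19), Gjd2 (0.58 ± 0.12) and Prnp (0.92 ± 0.21), with adjusted p from 0.126 to 0.259. The 3 Nasp probes ran from -1.48 to 0.59 and the 2 Gjd2 probes from -0.08 to 0.58.

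As lists, neuroendocrine peptides (17 measured, 0 called; 4 lower when adjusted over the list alone; median -0.42, adjusted p = 1.34e-05), striatal-type genes (21 measured, 0 called; 2 lower over the list alone; median -0.26, adjusted p = 4.18e-05) and pituitary markers (4 measured, 0 called; 2 lower over the list alone; median -0.99, adjusted p = 0.000199) were lower in N171-82Q saline mice. They had adjusted p-values of 0.0490, 0.0276 and 0.0275 with an estimated correlation, and these depended on single mice. Without WT saline 1, WT saline 3 or N171-82Q saline 15 none of the 3 passed with an estimated correlation (adjusted p from 0.0547 to 0.189), and pituitary markers failed with the preset one without WT saline 3 (adjusted p = 0.0848). The pituitary median was -0.18 without WT saline 3 and -1.55 without WT saline 1. Without N171-82Q saline 14, the lowest of its group for the first 2 lists, the medians were -0.44, -0.16 and -0.99 (adjusted p = 0.0623, 0.0363 and 0.0247 with an estimated correlation). A further 10 lists were lower with the preset correlation and had adjusted p from 0.0627 to 0.234 with an estimated one. Hypothalamic neuron genes (median -0.57, adjusted p = 0.0627 with an estimated correlation) and meninges and fibroblast markers (median -0.84, adjusted p = 0.234) were among them. Without the 2 arrays with doubted Prnp, Prnp alone was called. Those arrays are in neither group compared and were picked for their Prnp level. Leaving them out narrows the shared spread of Prnp, so this call adds no support. Fitted on the saline arrays alone 3 probes were called. The count was 8 without N171-82Q insulin 16, which is in neither group compared. That mouse enters through the shared spread, the normalization and the detection filter, which were not told apart.

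GLP-1Tf in N171-82Q mice was the 1 agent comparison in this genotype with called probes. Syne1, a nuclear envelope protein, fell from 9.72 ± 0.04 with saline to 8.80 ± 0.12 (SD, n = 3 each), a change of -0.93 ± 0.14 (SE, adjusted p = 0.0208). AI504432 (-1.62 ± 0.27, adjusted p = 0.0315), Msi2h, the RNA-binding protein Musashi 2 (-1.34 ± 0.22, adjusted p = 0.0315), Flrt2, a cell adhesion protein (-1.02 ± 0.17), Btbd3 (-1.24 ± 0.22), and Kif1b, a kinesin motor of axonal transport (-1.16 ± 0.21, each adjusted p = 0.0403), fell as well. Zzz3 fell by at least 1.64-fold (adjusted p = 0.0403), since it was detected on 0 of 3 GLP-1Tf arrays and 3 of 3 saline arrays. All 7 were lower on 3 of 3 GLP-1Tf arrays with no overlap with saline, and no probe was called higher. At 3 against 3, chance gives no overlap, in one direction or the other, for 10% of probes, and these 7 were picked on the same arrays. Of the 6 Kif1b probes tested, changes ran from -1.16 to 0.03, and the other genes with more than 1 probe, Syne1, Btbd3 and Zzz3, had changes of the same sign. The 2 Syne1 probes differed in size (-0.93 and -0.28). The 2 Btbd3 probes had -1.24 and -1.18, and the 4 Zzz3 probes ran from -1.16 to -0.56. None of the 29 lists passed. The 7 calls included none of the peptides that fell with genotype: Avp, Pomc, Vip, Ghrh, Cartpt, Trh and Hcrt were not called in this comparison.

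The count of 7 changed with the arrays used. It was 6 without the 2 arrays with doubted Prnp, 1 (another probe) when fitted on these 6 arrays alone, and 1141 with array weights. It was 0 without N171-82Q saline 13 or 15 or GLP-1Tf 20 or 21, 1 without WT insulin 4, WT Ex-4 10, N171-82Q insulin 18 or N171-82Q Ex-4 22, 23 or 24, 2 without WT Ex-4 11, 4 without WT insulin 6, WT GLP-1Tf 8 or N171-82Q insulin 17, and 13 without N171-82Q insulin 16.

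Ex-4 in N171-82Q mice gave no called probe (limma), with 785 at an unadjusted p under 0.05 against 704 expected. The probes of smallest p that did not pass were Polr1a, a subunit of RNA polymerase I, at least 5.16-fold higher with Ex-4 because it was undetected on all 3 saline arrays, A030007L17Rik (0.85 ± 0.19), Vamp8 (1.19 ± 0.27), Nasp (0.99 ± 0.24) and Mrpl35 (at least 1.24-fold higher) on the higher side. Msi2h (-0.90 ± 0.22), Slc43a2 (-0.58 ± 0.15), Csnk1g1 (-0.92 ± 0.25), Tpcn2 (-0.74 ± 0.20) and Srsf2 (-0.34 ± 0.09) stood on the lower side, all with an adjusted p of 0.786. The 3 Polr1a probes did not share a sign, nor did the 3 Srsf2 probes. Vamp8 had a change of 0.01 on its other probe and Csnk1g1 one of -0.17. The 2 Slc43a2 probes ran from -0.58 to -0.27 and the 3 A030007L17Rik probes from 0.34 to 0.85. With the preset correlation 7 lists were higher with Ex-4, among them appetite neuropeptides (median 0.19), hypothalamic neuron genes (median 0.26), glucocorticoid-responsive genes (median 0.28) and oxidative phosphorylation (median 0.07). Markers of thalamus (median 0.76), meninges and fibroblast (median 0.45) and cholesterol synthesis genes (median 0.11) moved with them. Without N171-82Q saline 14, appetite neuropeptides (adjusted p = 0.617), hypothalamic neuron genes (adjusted p = 0.564) and glucocorticoid-responsive genes (adjusted p = 0.226) no longer passed, and the first 2 did not pass without the array labelled N171-82Q Ex-4 24 (adjusted p = 0.548 and 0.313), whose Prnp is in doubt. Without N171-82Q saline 15 thalamus, meninges and fibroblast, and cholesterol synthesis did not pass (adjusted p = 0.248, 0.222 and 0.165), nor did meninges and fibroblast without N171-82Q Ex-4 22 (adjusted p = 0.0562). None of the 7 passed with an estimated correlation (adjusted p from 0.382 to 0.457), and no member of any was called or passed when adjusted over the list alone. With array weights 637 probes were called, and fitted on the 6 arrays alone 3 were.

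Insulin in N171-82Q mice also gave no called probe (limma), with 789 at an unadjusted p under 0.05. H1f2 (0.62 ± 0.16), Rpl7a (0.56 ± 0.14), Hmgb2 (0.62 ± 0.16), Polr3e (0.59 ± 0.16) and Ugt1a10 (at least 1.07-fold higher) had the smallest p on the higher side. Ehmt1 (-0.93 ± 0.21), AI504432 (-1.13 ± 0.27), Gal3st1, a sulphotransferase of myelin lipids (-0.62 ± 0.15), Esd (at least 2.38-fold lower) and Csnk1g1 (-0.97 ± 0.25) had it on the lower side, all with an adjusted p of 0.872. Glucocorticoid-responsive genes were higher as a list (17 measured, 0 called, 0 over the list alone; median 0.35, adjusted p = 1.80e-06; adjusted p = 0.574 with an estimated correlation), with Sgk1 at 0.93 ± 0.31 and Klf9 at 0.33 ± 0.12. Myelin genes were lower (15 measured, 0 called, 0 over the list alone; median -0.21, adjusted p = 0.0388; adjusted p = 0.729 with an estimated correlation), with Opalin at -0.60 ± 0.21 and Mag at -0.54 ± 0.20. The 4 Esd probes did not share a sign. With array weights 377 probes were called.

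In WT mice the same agents were set against the 2 saline mice. Aggf1, an angiogenic factor, fell with insulin from 6.69 ± 0.08 (SD, n = 2) to 5.32 ± 0.16 (SD, n = 3), a change of -1.38 ± 0.21 (SE, adjusted p = 0.0434), and was the 1 probe called among the 3 agents. It was detected on 2 of 2 saline and 2 of 3 insulin arrays, so its size is not exact. Nr4a2 had a change of -0.99 ± 0.16 with Ex-4 (adjusted p = 0.0888) and -0.82 ± 0.16 with GLP-1Tf (adjusted p = 0.282). Prl was undetected on all 3 arrays of each of these 2 agents, at least 1.27-fold lower with Ex-4 (adjusted p = 0.327) and at least 1.26-fold lower with GLP-1Tf (adjusted p = 0.245). Samd4 had a change of 3.53 ± 0.69 with Ex-4 (adjusted p = 0.327) and 3.06 ± 0.69 with GLP-1Tf (adjusted p = 0.344). Aggf1 with GLP-1Tf, detected on 1 of 3 arrays, had a change of -1.26 ± 0.21 (adjusted p = 0.133). The 4 Aggf1 probes ran from -1.26 to -0.18 in that comparison.

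Ex-4 and GLP-1Tf in WT mice gave 0 called probes each (limma), with 1044 and 515 at an unadjusted p under 0.05, and insulin gave 805 at that level. Fitted on the arrays of the comparison alone, 6 were called with Ex-4 and 0 with insulin. With 1 mouse left out, the insulin count was 0 for 14 of 23 mice, all 3 insulin mice among them, and 2 without WT GLP-1Tf 9, WT Ex-4 12 or N171-82Q saline 15. Aggf1 itself was called with 8 of the 23 mice left out in turn. Its call rests on both WT saline mice, since leaving out either leaves 1. The Ex-4 count was 1 without WT saline 1 and 3 without N171-82Q saline 15, and the GLP-1Tf count 1 without WT saline 1 or GLP-1Tf 8. As lists, meninges and fibroblast markers were lower with Ex-4 (9 measured, 0 called, 5 lower when adjusted over the list alone; median -0.99, adjusted p = 0.000107; adjusted p = 0.741 with an estimated correlation), as were pituitary markers (median -0.66; adjusted p = 0.0871 with an estimated correlation). Glycolysis genes were higher (median 0.13; adjusted p = 0.0871 with an estimated correlation). With GLP-1Tf the medians were 0.15 for glycolysis, -0.05 for striatal-type genes, -0.39 for pituitary and -0.18 for cortex and hippocampus (each adjusted p = 0.0488; adjusted p from 0.146 to 0.222 with an estimated correlation). With insulin, oxidative phosphorylation genes were lower (47 measured, 0 called, 0 over the list alone; median -0.19, adjusted p = 0.00316; adjusted p = 0.425 with an estimated correlation). The agents share the saline arrays, so part of any likeness between them comes from those arrays.

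Whether an agent acted differently in the 2 genotypes was tested as an interaction. No probe was called for Ex-4, GLP-1Tf or insulin (limma), with 918, 628 and 607 at an unadjusted p under 0.05. Probes of smallest p that did not pass for Ex-4 were Nr4a2 (1.07 ± 0.22), Ebpl (1.47 ± 0.30, with 0.34 on its other probe) and Cga, the common subunit of the pituitary glycoprotein hormones (5.63 ± 1.16), each with an adjusted p of 0.415. Cga was detected on 1 of 3 WT Ex-4 arrays and 1 of 3 N171-82Q saline arrays, so its size is not exact. For GLP-1Tf they were Nasp (2.07 ± 0.37, adjusted p = 0.257), Srsf10 and Gsk3b (1.00 ± 0.22, each adjusted p = 0.735), and for insulin Prl (adjusted p = 0.724), Nasp (1.71 ± 0.37) and Aggf1 (1.30 ± 0.28, each adjusted p = 0.873). No size is given for Srsf10, which was undetected on all 3 N171-82Q saline arrays, or for Prl, which was undetected on these and on all 3 WT insulin arrays. Pituitary markers differed by genotype in their Ex-4 effect (4 measured, 0 called, 2 higher when adjusted over the list alone; median 1.31, adjusted p = 0.000887; adjusted p = 0.0417 with an estimated correlation), the 1 of 11 list-by-agent interactions passing with the preset correlation that kept its call with an estimated one. Of the 4 groups in this interaction, Prl was detected on 2 of 2 WT saline arrays and on 0 of 3 arrays in each other group. Whether the list reads an agent effect or differing pituitary tissue in the blocks was not tested. The interaction rests on the 2 WT saline arrays, and fitted on its 4 groups alone the Ex-4 interaction had 5 called probes. With 1 mouse left out each interaction count was 0 or 1, the latter without WT saline 1 (Ex-4 and GLP-1Tf), WT GLP-1Tf 8 (GLP-1Tf) or N171-82Q insulin 16 (insulin).

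Ex-4 and GLP-1Tf both act on the GLP-1 receptor, the first as a peptide of reptile origin and the second as a peptide joined to transferrin, and insulin was the comparator. Their doses are given in different units, so they were compared as given. No probe was called between any 2 of them in N171-82Q mice (limma), with 691 at an unadjusted p under 0.05 for Ex-4 against GLP-1Tf, 597 for Ex-4 against insulin and 1320 for GLP-1Tf against insulin. The median 95% interval of a difference was ± 0.38 on the log2 scale, unadjusted, and larger differences than this can be missed after adjustment. Between Ex-4 and GLP-1Tf the smallest p belonged to Thsd4 (at least 1.69-fold higher with Ex-4), Olfr168 (at least 1.20-fold lower), Syne1 (0.65 ± 0.14), Trim9 (at least 5.04-fold lower) and Btbd3 (1.02 ± 0.22), with an adjusted p of 0.449. Between Ex-4 and insulin it belonged to the neuropeptide gene Cck (1.54 ± 0.32), Rgs16 (0.77 ± 0.16) and Trpm6 (at least 1.28-fold higher), with an adjusted p of 0.733. Between GLP-1Tf and insulin Rgs16, a regulator of G-protein signalling, led (0.91 ± 0.16, adjusted p = 0.310), before Esd (at least 2.80-fold higher) and Wnt4 (0.81 ± 0.17).

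Thalamus markers were higher with Ex-4 than with insulin (6 measured, 0 called, 4 higher when adjusted over the list alone; median 1.28, adjusted p = 2.17e-07; adjusted p = 0.269 with an estimated correlation), with Prkcd at 1.59 ± 0.40 and Tnnt1 at 1.96 ± 0.53. Whether the blocks of these groups held different amounts of thalamus was not tested. Myelin genes stood higher as well (median 0.35; adjusted p = 0.269 with an estimated correlation), as did oxidative phosphorylation (median 0.10; adjusted p = 0.592) and meninges and fibroblast markers (median 0.48; adjusted p = 0.720). Against GLP-1Tf, Ex-4 had medians of 0.29 for glucocorticoid-responsive genes, 0.47 for thalamus, 0.55 for meninges and fibroblast, and 0.09 for oxidative phosphorylation (each adjusted p = 0.708 with an estimated correlation). GLP-1Tf against insulin had medians of -0.46 for glucocorticoid-responsive genes, with Sgk1 at -1.28 ± 0.31, and 0.28 for myelin genes (each adjusted p = 0.702 with an estimated correlation). With array weights the 3 comparisons had 998, 32 and 41 called probes, and fitted on the 6 arrays alone Ex-4 against GLP-1Tf had 5. GLP-1Tf against insulin had 1 without WT saline 1 or 3.

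A genotype signature score asked whether an agent moved N171-82Q mice toward WT. For each agent the 100 probes of smallest p for genotype were taken from the arrays of the other 2 agents, so the score shared no array with its test. Higher scores lie further in the N171-82Q direction. With Ex-4 the score was 0.24 ± 0.22 against 0.37 ± 0.74 with saline (SD, n = 3 each), a difference of -0.12 (exact 2-sided permutation p = 0.8). GLP-1Tf gave 0.30 ± 0.04 against 0.43 ± 0.72, a difference of -0.13 (exact permutation p = 0.7, n = 3 each). Insulin gave 0.39 ± 0.62 against 0.19 ± 0.62, a difference of 0.20 (exact permutation p = 0.6, n = 3 each). The adjusted p over the 3 tests was 0.8 each, and 3 mice against 3 cannot give a p below 0.1. On the 3 scores in this order, WT saline mice averaged -0.98, -0.55 and -0.50 (n = 2), and WT mice given the same agent 0.05 ± 0.47, -0.37 ± 0.41 and -0.25 ± 0.22 (SD, n = 3 each). WT Ex-4 mice thus lay closer on average to N171-82Q Ex-4 mice than to WT saline mice. Saline mice of the 2 genotypes were apart on the Ex-4 score (WT -1.32 to -0.64, N171-82Q -0.37 to 1.12). On the GLP-1Tf and insulin scores they overlapped (WT up to -0.19 and -0.31, N171-82Q from -0.29 and -0.47). These 2 scores thus did not part the untreated genotypes and could hardly measure a move toward WT. All 3 differences between agent and saline were smaller than the spread between saline mice, and each changed sign without at least 1 of N171-82Q saline 14, saline 15 or insulin 16.

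**Figure D3:**
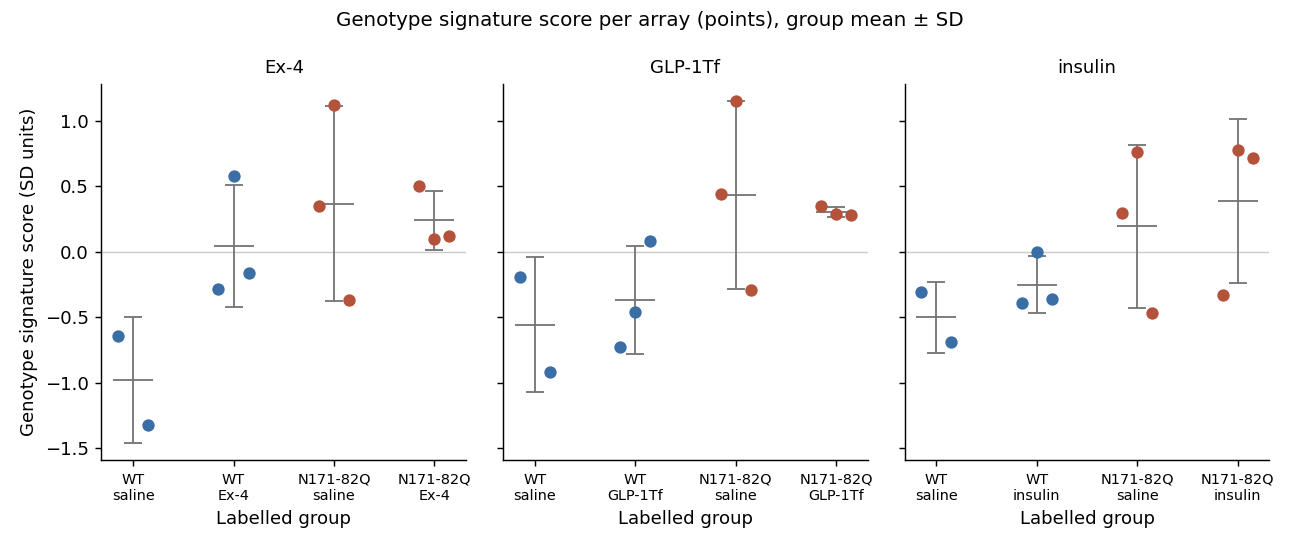
Genotype signature score (mean of signed, probe-standardised values, in SD units) of each array, in 1 panel per agent with its own signature; points are mice, bars and whiskers the group mean ± SD, and the x axis gives labelled groups. The 3 N171-82Q saline mice span -0.37 to 1.12, -0.29 to 1.15 and -0.47 to 0.76, wider than the differences between agent and saline.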

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

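The interaction tests below were set before the data were examined, and 11 list-by-agent tests, on 8 different gene lists, showed a different agent effect in N171-82Q and WT mice with the preset correlation. For Ex-4, the list medians in N171-82Q and WT mice were 0.45 and -0.99 for meninges and fibroblast markers (interaction adjusted p = 8.70e-07; adjusted p = 0.220 with an estimated correlation) and 0.66 and -0.66 for pituitary markers (adjusted p = 0.000887; adjusted p = 0.0417 with an estimated correlation). They were 0.07 and -0.05 for oxidative phosphorylation (adjusted p = 0.000887; adjusted p = 0.262 with an estimated correlation), 0.11 and -0.02 for cholesterol synthesis (adjusted p = 0.0236; adjusted p = 0.220 with an estimated correlation), and 0.09 and -0.15 for striatal-type genes (adjusted p = 0.0295; adjusted p = 0.220 with an estimated correlation). For GLP-1Tf they were 0.09 and -0.12 for incretin, insulin and leptin signalling (adjusted p = 0.0125; adjusted p = 0.163 with an estimated correlation) and 0.09 and -0.05 for striatal-type genes (adjusted p = 0.0154; adjusted p = 0.245 with an estimated correlation).

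For insulin the medians in N171-82Q and WT mice were 0.35 and -0.20 for glucocorticoid-responsive genes (adjusted p = 1.44e-07; adjusted p = 0.326 with an estimated correlation) and 0.03 and -0.19 for oxidative phosphorylation (adjusted p = 0.00108; adjusted p = 0.498 with an estimated correlation). They were 0.26 and -0.70 for pituitary markers (adjusted p = 0.00359; adjusted p = 0.0894 with an estimated correlation) and -0.47 and 0.24 for thalamus markers (adjusted p = 0.0330; adjusted p = 0.685 with an estimated correlation). All 11 interactions rest on the same 2 WT saline arrays and the same 3 N171-82Q saline arrays, so they are not independent of each other across agents. For pituitary, thalamus, and meninges and fibroblast markers, a difference in the tissue the blocks held was not tested.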

How the results depend on the processing

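The array weights, the filters, the scalings and leaving out mice were set before the data were examined, and leaving out the 2 arrays with doubted Prnp and array brightness as a covariate were chosen after. Genotype averaged over agents had 113 called probes (27 higher), and counts of 124 (32 higher) with no background correction, 68 (12 higher, 66 of the 113 shared) with per-array Z-scores, 51 (6 higher) with no detection filter, 117 with the stricter filter, 59 (11 higher) with the deposited scores, 198 without the 2 doubted arrays and 50 (8 higher) with the brightness covariate. Array weights gave 1380, and 637, 1141 and 377 for Ex-4, GLP-1Tf and insulin in N171-82Q mice, 0 for insulin in WT mice, and 998, 32 and 41 for Ex-4 against GLP-1Tf, Ex-4 against insulin and GLP-1Tf against insulin. These weights were 5.73 for N171-82Q saline 13 against 0.25 and 0.34 for its group's other 2 mice, so the agent fits against N171-82Q saline lean on 1 mouse.

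Fits on only the groups compared, with fewer arrays to estimate the spread, called 3 probes for genotype in saline mice, 3 for Ex-4 and 1 for GLP-1Tf in N171-82Q mice (0 of the 7 shared), 6 for Ex-4 and 0 for insulin in WT mice, 5 for the Ex-4 interaction and 5 for Ex-4 against GLP-1Tf. With no background correction Ex-4 in WT mice had 1 and insulin in WT mice 2. Insulin in WT mice had 0 with no detection filter and 0 with the brightness covariate, which gave GLP-1Tf in N171-82Q mice 12. Without the doubted arrays genotype in saline mice had 1, Prnp, for whose level those arrays were picked, and the insulin signature score difference turned to -0.03. The cause was not tested for the other changes.

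With 1 mouse left out in turn, counts ran from 0 to 8 for genotype in saline mice, 23 to 480 for genotype averaged over agents, 0 to 13 for GLP-1Tf in N171-82Q mice, 0 to 3 for Ex-4, 0 to 1 for GLP-1Tf and 0 to 2 for insulin in WT mice, 0 to 1 for each interaction and for GLP-1Tf against insulin, and stayed 0 for the other 4 comparisons. Where this left WT saline with 1 mouse, that mouse was assumed to vary like the other groups. Signature differences ran from -0.49 to 0.49 for Ex-4, -0.49 to 0.47 for GLP-1Tf and -0.13 to 0.60 for insulin.

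Of 66 list calls, 9 held with an estimated correlation. Oxidative phosphorylation for Ex-4 against GLP-1Tf reversed with Z-scores (adjusted p = 0.545), where 11 others no longer passed, and 12 no longer passed without the doubted arrays and 12 with brightness. With no background correction all 66 kept their direction and call. Among probes named and called, 19 of 39 lost their call with no detection filter, 12 with brightness, 9 with Z-scores, 9 with the deposited scores and 5 without the doubted arrays. Probes named but not called have no called direction, so a sign change there was counted as moved, which happened 30 times with mice left out and for 5 probes with Z-scores. The scalings moved the median of all probes by under 0.1. Slide as a block was not run, since no slide is named in the sources used here, and a fit on only the groups compared is the same fit for genotype averaged over agents. Probes near the negative controls, such as those named for Tnxb, Socs3 and Crabp1, are limited by signal over background.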

Other observations

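The tests of array labels, of dissection, of brightness and of the 7 GLP-1Tf probes, the agent effects averaged over genotypes with their splits, and the genes of the next paragraph were chosen after the results were seen, and the tests of dissection and of the Prnp probe were replaced after their first values were seen. The other splits of the arrays were set before.

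Further called genes were picked by eye from the 113 probes of the genotype comparison averaged over agents, and no theme was tested. Stat3, the transcription factor that induces Socs3, fell by 0.47 ± 0.08 in N171-82Q mice (SE, limma adjusted p = 0.00818) and Lbp, the lipopolysaccharide-binding protein, fell by 0.58 ± 0.10 (adjusted p = 0.0136), beside the falls of Socs3, C3 and Serpina3n. Each was below the WT mean on 12 of 12 N171-82Q arrays, the arrays on which they were called, and Lbp was detected on 3 of 12 against 11 of 11. Casp1 was called higher (0.40 ± 0.09, adjusted p = 0.0453), and the inflammation and interferon list did not pass with an estimated correlation (adjusted p = 0.252). Tnxb was lower on 3 probes, 2 of them by 0.94 ± 0.11 and 0.70 ± 0.10 (adjusted p = 0.000566 and 0.00537) and the other undetected on all 12 N171-82Q arrays and on 7 of 11 WT arrays, so that no size is given. Also lower were the collagen gene Col6a1 (-0.50 ± 0.11, adjusted p = 0.0363), the collagen and elastin crosslinking enzyme Loxl1 (-0.55 ± 0.12, adjusted p = 0.0413) and Dag1, a laminin receptor (-0.53 ± 0.12, adjusted p = 0.0427). The meninges and fibroblast list did not pass with an estimated correlation (adjusted p = 0.315). Th, the rate-limiting enzyme of dopamine synthesis, fell by 0.41 ± 0.08 (adjusted p = 0.0330), and Crhbp, which binds corticotropin-releasing hormone, fell by 0.37 ± 0.08 (adjusted p = 0.0432).

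The first pattern is the Prnp level of the arrays labelled WT GLP-1Tf 9 and N171-82Q Ex-4 24. A misread of the Prnp probe alone would leave other genes in place, but of 100 genotype probes other than Prnp, chosen without the pair, 21 put both arrays outside the range of their labelled genotype, toward the other. As many were found for 4 of 111 pairs of a WT and an N171-82Q array, this pair included (median of the others 1, highest 43). That share is under 0.05, but the pairs reuse the same arrays, and 3 pairs with Prnp in their own range had more. Singly, WT GLP-1Tf 9 lay outside on 33 probes and N171-82Q Ex-4 24 on 43, against up to 63 and 76 for other arrays. The count therefore cannot decide whether the Prnp probe alone was misread. On a score from 100 such probes, 2 of the 2 arrays lay on the other genotype's side of the midpoint (0.15 and -0.22), but so did 3 of the other 21, so an exchange of the 2 labels may explain the pattern and is not shown. A mixed sample or a wrong genotype call for a single mouse was not tested and stays open too.

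The second pattern is the lower level of some hypothalamic peptides in N171-82Q mice. Brightness of the arrays as a covariate left a median of -0.50 for the hypothalamic neuron list (camera adjusted p = 2.70e-09 with the preset correlation). This argues against brightness as the cause of the list's fall. An estimated correlation was not run with that covariate. It left 50 called probes, 49 of them among the 113, so the argument does not cover single probes. Less hypothalamus in the N171-82Q blocks may also be the source: 13 of 14 hypothalamic neuron genes were lower, Hap1 among them (-0.35 ± 0.15), and thalamus markers (median 0.44, Tcf7l2 0.59 ± 0.17 and Tnnt1 0.66 ± 0.27, but Zic1 -0.12 ± 0.13 and Slc17a6 0.02 ± 0.08) were higher with the preset correlation (adjusted p = 0.0446) and not with an estimated one (adjusted p = 0.400), while those of the other neighbours were not higher (striatum, median -0.14; cortex and hippocampus, median -0.01). The falls were uneven, with 4 of the 14 intervals above the list median of -0.52. They were those of Oxt (0.05, 95% interval -0.27 to 0.37), Pmch (-0.23), Peg10 (-0.23) and Calcr (-0.05). Calcr was detected on 4 of 12 N171-82Q and 3 of 11 WT arrays, and Peg10 was dim (mean 5.68). These 2 could therefore show little of a fall. A block that lost some hypothalamic regions and not others was not tested. Dissection therefore cannot be told apart from an effect of the transgene, the biological difference the design names. As many probes as the real 113 were called in 2 of 100 splits of the arrays, the real one included, a share under 0.05. This covers the count of all called probes and not the peptides as such. The highest other split called 2450. Its sides differed on the first principal component (43.3% of that component's variance, against 5.4% for genotype). Genotype differed on component 3 (40.9%, against 1.2% for that split). The split was picked for its count, so its component is a description and not separate evidence of a structure.

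The third pattern is the 7 probes lower with GLP-1Tf in N171-82Q mice. Against the same saline arrays they had medians of -0.42 with Ex-4 and -0.65 with insulin in N171-82Q mice, beside -1.16 with GLP-1Tf, but these saline arrays served to pick the probes. In WT mice, which did not, 7 of 7 were lower with each agent (medians of -0.72 for GLP-1Tf, -0.63 for insulin and -0.23 for Ex-4, the smallest 32% of the GLP-1Tf change), but these values rest on the 2 WT saline arrays and cannot show whether the N171-82Q saline arrays stood apart, so that explanation may hold and an effect of GLP-1Tf cannot be told apart from it. Averaged over genotypes, GLP-1Tf had 24 called probes (23 lower; 3 without the 2 doubted arrays), Ex-4 0 and insulin 0 (limma; 1037 and 1113 at an unadjusted p under 0.05). As many as 24 were called in 5 of 100 splits, so chance cannot be excluded. The highest other split called 1132, and its sides differed on the first principal component (63.5%), but it was picked for its count.

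For comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. GLP-1Tf in N171-82Q mice called 7 probes and the highest other split 0, with 1 of 10 splits reaching 7. For Ex-4 and insulin in N171-82Q mice, Ex-4 against GLP-1Tf, Ex-4 against insulin and GLP-1Tf against insulin the real count was 0, which 10 of 10 splits reach in each, and the highest other splits called 0, 31, 0, 0 and 3. The sides of the split with 31, where the real one had 0, differed on principal components 2 and 3 (65.3% and 64.4% of their variance over the 6 arrays, against 0.3% and 4.0% for insulin). That split was picked for its count, so this is a description and not separate evidence of a structure.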
